A study of Homo sapiens with 7 samples.

How the data were processed

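The deposited table held counts of reads per guide RNA for 7 libraries, with the sequence of each guide and a gene symbol, and was used as deposited. Per the labels' protocols, NK-92 cells of one Cas9 clone were transduced with the Brunello knockout library in a puromycin resistance vector, selected, kept in culture and stimulated with PMA and ionomycin, and fixed CD56-positive cells were sorted by CD107a staining with RAB27A knockout cells as gating controls. Unsorted cells were neither stimulated nor stained, per the labels, and were taken on day 9 and day 17. Guide cassettes were amplified by PCR from genomic DNA or plasmid and sequenced as single-end reads, per the labels' protocols. The table has the layout that PoolQ writes; the version of that tool, its matching rule and any filters are not given in the sources used here. The counts are whole numbers that had not been normalized, judged from library totals that differ. The reads carry no molecular identifiers, so a count includes PCR duplicates, and fixed cells may give fewer usable genomes than unfixed cells.

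Libraries were grouped by the names in the labels: CD107a negative (2 libraries), CD107a high (2), day 9 unsorted, day 17 unsorted and plasmid library (1 each). There were 0 unused sample columns. Each column was assigned by its library name. Of 19114 genes, 19107 had 4 guides, 6 had 2 and 1 had 1; the remaining 1000 guides were non-targeting. Gene symbols were matched to the RefSeq annotation of GRCh38.p14 for current names and for the order of genes along chromosomes, with no coordinates used: 17852 were current symbols, 1135 matched through a synonym and 127 were not matched. Guides that also match a paralog, or that cut at several places, were not looked for, so values of genes with near-identical copies are uncertain.

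For CD107a negative over CD107a high, guides with a mean of at least 1 CPM (reads scaled to library size) over the 4 sorted libraries were kept (72497, of which 990 were non-targeting). They were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization and no covariate. The common dispersion was 0.347, a biological coefficient of variation of 58.9%. Each guide's p was turned into a signed z value, and the guides of each gene with at least 3 guides were tested as a set with cameraPR of limma 3.58.1 (parametric, preset correlation 0.01), two-sided, with Benjamini-Hochberg adjustment over 17883 genes and a threshold of 0.05. The effect of a gene is the mean of its guides' fitted log2 ratios with the SD over guides, and positive values mean more reads in CD107a negative cells. Values for each sort are log2 ratios of CPM plus 1. Gene lists were tested in the same way, with all guides of their genes as one set and adjustment over the 23 fixed lists, and again by camera with an estimated correlation. That second test has 2 residual degrees of freedom, which raises its p whatever the correlation. Correlations of effects between the sorts and between growth and sort are across genes.

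The 23 lists were cytotoxic granule exocytosis; palmitoyl transferases and partners; depalmitoylating enzymes; de novo ceramide synthesis; sphingolipid conversion, breakdown and control; fatty acid supply; PKC, calcium and ERK signalling; SNAREs and SM proteins; Rab geranylgeranylation; exocyst; HOPS, BLOC and AP-3; V-ATPase; conserved oligomeric Golgi complex; N-glycan processing and sialylation; cortical actin regulators; NK receptors and proximal signalling; IL-2 receptor signalling; negative regulators of growth; cytosolic ribosomal proteins; proteasome; mitochondrial ribosomal proteins; olfactory receptors; and the readout and gate pair of LAMP1 and NCAM1. A further 12 lists were chosen after the values had been seen and serve only the closing observations. Lists share members: STXBP2, STX11, VAMP8 and SNAP23 are in both the granule exocytosis and the SNARE list.

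The comparisons, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule named the 20 called genes with the smallest p that were higher in CD107a negative cells and the 10 that were higher in CD107a high cells, if both sorts had the same sign. It added called members of the lists on granule exocytosis, palmitoylation, depalmitoylation and sphingolipids, and always RAB27A, UNC13D, STX11, STXBP2, LAMP1 and NCAM1. Of other lists it took 2 to 4 members with the smallest p, and for growth the 10 lowest and 10 highest genes on day 17 among those with at least 3 guides that all go one way. A gene named by this rule is not reported here. Outside this rule, AP3B1, TECR, ABHD17A, the sort values of IFNAR2, TYK2 and IRF9, members that passed over their list alone, growth values of list members and of called genes, and the genes of the closing observations were chosen after their values were seen.

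The single libraries of day 9, day 17 and plasmid were compared without a test. For guides with at least 1 CPM in the earlier library, the log2 ratio of CPM plus 1 was averaged over each gene's guides and centred on the median of the non-targeting guides, and genes at or below -1 or at or above 1 were counted. This scale understates the change of guides near zero. A list's median was placed among 10000 random lists of the same size matched on plasmid abundance, and its percentile describes these libraries only. The interval of the correlation between growth and sort effects came from 1000 bootstrap draws of genes.

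The gene tests were tested on simulated data drawn from the guide means, fitted dispersions and library sizes of the sorted libraries, with 100 of 17883 genes changed by 2-fold and 100 by 4-fold. cameraPR recovered 41 of the 100 genes at 2-fold and 88 at 4-fold, with 3 false among 132 calls. Rank aggregation recovered 29 and 80, with 1 false among 110 calls. With no change simulated, cameraPR called 0 genes, and 770 had an unadjusted p under 0.05. All guides of a changed gene were given the same change, whereas guides of called genes differed in the data. These rates may therefore not hold for the screen.

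The alternatives for the sort were DESeq2 1.42.0 size factors, total counts or non-targeting guides for scaling; no guide filter or a mean of 5 CPM; DESeq2 Wald statistics in place of edgeR; the sort number as a block; leaving out each sorted library; rank-based cameraPR, camera with an estimated correlation, fry, and an own version of robust rank aggregation (alpha 0.25, 1e+06 random guide sets); and leaving out each gene's strongest guide. With 1 library left out, the lone library of a population was assumed to vary like the others. For growth they were pseudocounts of 0.1 and 5, no filter or 5 CPM, the median over guides, and no centring. Pseudo-genes were random groups of 4 non-targeting guides. Low guide abundance limits mainly the depleted genes, because genes with fewer than 3 guides past the filter were left out of the sort. Guides under 1 CPM numbered 7068 in CD107a negative 1, with 52054392 reads, and 9651 in CD107a negative 2, with 93217525 reads. The library with more reads thus had more such guides, so read depth does not account for the difference between these libraries. The cause of that difference was not tested.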

Results

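The screen was run in NK-92, a human natural killer cell line, in a Cas9-expressing clone that had received the Brunello guide RNA library, so that the guide sequence in a cell marks the gene it targets. The cells were stimulated with PMA and ionomycin, which release lytic granules without a target cell. Granule release brings CD107a, the lysosomal membrane protein encoded by LAMP1, to the cell surface, and CD56-positive cells were sorted into CD107a negative and CD107a high populations. Guide sequences were then read from genomic DNA. There were 2 CD107a negative and 2 CD107a high libraries, from sorts 1 and 2, and single libraries of unsorted cells on day 9, of unsorted cells on day 17, and of the plasmid library. The total was 52054392 reads in CD107a negative 1, 93217525 in CD107a negative 2, 55696806 in CD107a high 1, 83431466 in CD107a high 2, 56925821 on day 9, 64032517 on day 17 and 95426821 in the plasmid library.

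Of the guides in the table, 1000 were non-targeting and the other 76441 addressed 19114 genes. Guides without a read made up 0.0762% of the plasmid library (Wilson 95% interval 0.0591 to 0.0983), 0.391% on day 9 (0.350 to 0.438) and 0.600% on day 17 (0.548 to 0.657). In the sorted cells the share was 0.890% (0.826 to 0.958) in CD107a negative 1, 0.615% (0.562 to 0.672) in CD107a negative 2, 0.783% (0.723 to 0.847) in CD107a high 1 and 0.656% (0.602 to 0.715) in CD107a high 2. These intervals cover counting error only, because PCR reads without molecular identifiers are not independent molecules. The Gini coefficient of guide abundance, 0 for an even library, was 0.291 in the plasmid library, 0.344 on day 9, 0.424 on day 17 and between 0.450 and 0.486 in the sorted libraries. The most abundant guide targeted IFNAR1 on day 17 and in both CD107a negative libraries and IFNAR2 in both CD107a high libraries, with 0.0568% to 0.0744% of the reads. Spearman correlations of guide abundance across guides were 0.771 between the CD107a negative libraries, 0.812 between the CD107a high libraries, 0.813 between the populations of sort 1 and 0.729 between those of sort 2.

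The comparison of CD107a negative with CD107a high cells asked which knockouts lower or raise degranulation, and the series title names palmitoylation and sphingolipid metabolism among its subjects. Guides against 5 of the 24 measured genes of the cytotoxic granule exocytosis list were enriched in CD107a negative cells. STXBP2, the Munc18 protein that holds syntaxin 11, reached a mean log2 ratio of 1.76 ± 0.47 (SD over guides, n = 4 guides here and throughout unless stated), a 3.39-fold enrichment. Its partner STX11, a plasma membrane syntaxin, reached 1.36 ± 0.57, and VAMP8, a SNARE of vesicle membranes, reached 1.76 ± 0.96. RAB27A, the GTPase that brings granules to the membrane and whose knockout served as the gating control, had 1.60 ± 0.53, with 0.88 in sort 1 and 2.43 in sort 2. SNAP23, a plasma membrane SNARE, had 1.89 ± 1.03 (n = 3 guides). LAMP1, which encodes the stained protein itself, was 4.84-fold enriched, with 2.27 ± 0.64.

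Of the 24 measured genes of the cytotoxic granule exocytosis list, these 5 were called in the CD107a negative direction and none in the other, with cameraPR adjusted p of 2.67e-08 for STXBP2, 0.000343 for STX11, 0.00897 for VAMP8, 0.0115 for RAB27A and 0.0145 for SNAP23. UNC13D, which primes granules for fusion, had 1.06 ± 0.56 and was not called (cameraPR adjusted p = 0.235). Adjusted over the list alone, 6 genes were higher in CD107a negative cells, UNC13D among them (cameraPR adjusted p = 0.00600), and AP3B1, a subunit of the AP-3 coat, was higher in CD107a high cells at -2.45 ± 2.29 (cameraPR adjusted p = 0.0212). The list as a whole was shifted toward CD107a negative cells (cameraPR adjusted p = 1.68e-07, and adjusted p = 0.178 with an estimated correlation). That correlation was estimated at -0.00408, below the preset 0.01, so the larger p did not come from correlated guides. The pair of LAMP1 and NCAM1, the latter encoding the CD56 used for gating, was also shifted (cameraPR adjusted p = 0.000725, adjusted p = 0.263 with an estimated correlation), with LAMP1 called at 7.77e-08 and NCAM1 not called at -0.66 ± 0.69 (n = 3 guides, cameraPR adjusted p = 0.862). Adjusted over the list alone, LAMP1 remained the single call of that pair. STXBP2 and LAMP1 were called whichever sorted library was left out, whereas without CD107a negative 1 the cameraPR adjusted p was 0.306 for RAB27A and SNAP23, 0.183 for VAMP8 and 0.0520 for the LAMP1 and NCAM1 pair, and 0.387 for UNC13D over the list alone. Without CD107a negative 2 it was 0.0634 for STX11, and without CD107a high 1 it was 0.199 for AP3B1 over the list alone. SNAP23 was also lost without a guide filter (cameraPR adjusted p = 0.342).

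**Figure D1:**
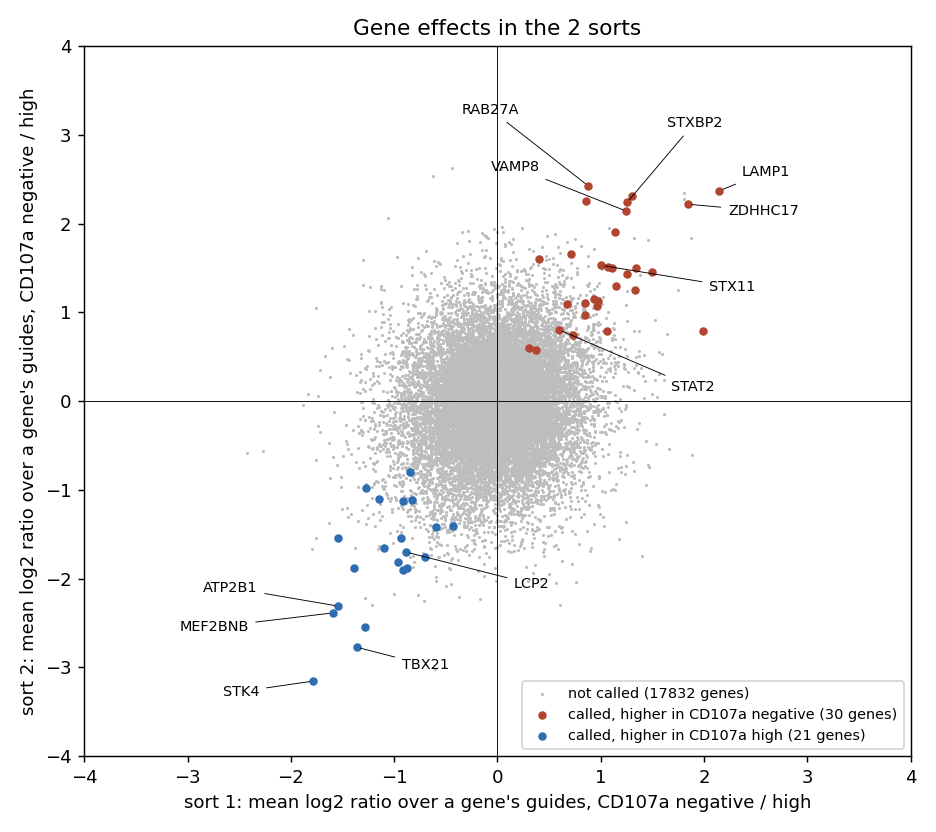
Each point is a gene, with the mean log2 ratio of its guides in CD107a negative over CD107a high cells of sort 1 on the x axis and of sort 2 on the y axis. The 30 genes called higher in CD107a negative cells and the 21 called higher in CD107a high cells lie in the quadrants where both sorts have the same sign. Calling used both sorts together and so favours this. Over all 17883 genes Pearson's r is 0.134.

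The exocyst, the complex that tethers vesicles to the plasma membrane, had the smallest p of the 23 lists. Of its 11 measured genes, 4 were enriched in CD107a negative cells: EXOC6 at 1.44 ± 0.31, EXOC1 at 1.46 ± 0.65, EXOC8 at 1.42 ± 0.69 and EXOC7 at 1.11 ± 0.40, with cameraPR adjusted p between 0.0134 and 0.0258. Adjusted over the list alone there were 6, with RALA, a small GTPase that binds the exocyst, at 0.85 ± 0.27 (cameraPR adjusted p = 0.0124) and EXOC4 at 1.08 ± 1.04 (0.0238). The list had a cameraPR adjusted p of 6.78e-10, and an adjusted p = 0.178 with an estimated correlation (estimated at -0.0200). Single exocyst genes depended on single libraries: without CD107a negative 1 the cameraPR adjusted p was 0.306 for EXOC6 and EXOC1, 0.511 for EXOC7, and over the list alone 0.0612 for RALA and 0.335 for EXOC4, and without CD107a high 1 it was 0.349 for EXOC8. Among the 43 measured SNAREs and their SM partners, STXBP2, STX11, VAMP8 and SNAP23 were enriched in CD107a negative cells, both over all genes and adjusted over the list alone. The median of that list was -0.09 although its mean z was 0.10, and its cameraPR adjusted p was 0.834.

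Of the 26 measured palmitoyl transferases and partners, ZDHHC17 alone was called, both over all genes and adjusted over the list alone. ZDHHC17, a palmitoyl transferase of the Golgi, was 5.18-fold enriched in CD107a negative cells at 2.37 ± 1.05 (cameraPR adjusted p = 0.000104). Of 16 alternative settings, 12 kept its call and 4 lost it. The 4 include rank-based cameraPR, camera with an estimated correlation and fry, which called no gene at all. The next genes of that list, ZDHHC23 at -0.76 ± 1.26 (n = 3 guides) and ZDHHC15 at 0.22 ± 0.28, were not called, and the list did not shift (cameraPR adjusted p = 0.994, median -0.15, mean z 0.02). None of the 11 depalmitoylating enzymes was called by cameraPR over all genes or over the list alone, with ABHD17A at -1.73 ± 1.73 nearest, and their list adjusted p was 0.601. In sphingolipid metabolism, COL4A3BP, now named CERT1, which carries ceramide from the endoplasmic reticulum to the Golgi, was enriched in CD107a negative cells at 1.09 ± 0.35 (cameraPR adjusted p = 0.0193, but 0.370 without CD107a negative 2). It was the single call among 36 genes of sphingolipid conversion, breakdown and control, also adjusted over the list alone, and that list had a cameraPR adjusted p of 0.834.

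None of the 14 genes of de novo ceramide synthesis was called by cameraPR over all genes. Adjusted over the list alone, the serine palmitoyltransferase subunits SPTLC1, at 1.85 ± 1.71, and SPTLC2, at 2.86 ± 1.62 (n = 3 guides), were higher in CD107a negative cells (cameraPR adjusted p = 0.0186 each). DEGS1, the desaturase of the last step, was higher in CD107a high cells at -1.72 ± 1.53 (0.0347). Without CD107a negative 1 these 3 values became 0.143, 0.139 and 0.143, and DEGS1 was lost whichever library was left out. The list of 14 genes had a cameraPR adjusted p of 0.834. The 22 measured genes of fatty acid supply held no call over all genes or over the list alone (cameraPR adjusted p = 0.834 for the list); TECR, an enoyl reductase of fatty acid elongation, was nearest at -1.11 ± 0.86.

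In calcium signalling, PPP3R1, the regulatory subunit of calcineurin, was enriched in CD107a negative cells at 1.55 ± 0.42 (cameraPR adjusted p = 0.00335) and so was the calcium channel subunit ORAI2 at 1.64 ± 0.27 (0.0125). The protein kinase C isoform PRKCH was enriched in CD107a high cells at -1.17 ± 0.74 (cameraPR adjusted p = 0.00450). These were the 3 calls among 37 genes of the PKC, calcium and ERK list, and PPP3CA, the catalytic subunit of calcineurin, joined them adjusted over the list alone at 0.98 ± 0.62 (cameraPR adjusted p = 0.0353). The list itself did not shift (cameraPR adjusted p = 0.902). Without CD107a negative 1 the cameraPR adjusted p was 0.143 for PPP3R1, 0.584 for ORAI2 and 0.380 for PRKCH, and without CD107a high 2 it was 0.415 for PPP3CA over the list alone.

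In the response to type I interferon, STAT2 at 0.70 ± 0.26 and the receptor subunit IFNAR1 at 0.45 ± 0.30 were called higher in CD107a negative cells, while IFNAR2 at 0.14 ± 0.18, TYK2 at 0.21 ± 0.14 and IRF9 at 0.34 ± 0.32 were not called. The cameraPR adjusted p was 1.84e-08 for STAT2 and 0.00117 for IFNAR1. STAT2 was called whichever sorted library was left out. IFNAR1 was lost in each case, with a cameraPR adjusted p of 0.268 without CD107a negative 1, 0.1003 without CD107a negative 2, 0.230 without CD107a high 1 and 0.647 without CD107a high 2. Without a guide filter the cameraPR adjusted p was 0.0703 for STAT2 and 0.660 for IFNAR1. IFNAR1 lies on chromosome 21, whose 203 tested genes apart from IFNAR1 and IFNAR2 had a median of 0.27. The polycomb subunits EED, of the complex that methylates histone H3, and PCGF1 were enriched at 1.02 ± 0.29 and 0.94 ± 0.31 (cameraPR adjusted p = 0.000730 and 0.00315). PLEK, or pleckstrin, a substrate of protein kinase C, was enriched at 1.31 ± 0.50 (cameraPR adjusted p = 0.000624). The splicing regulator HNRNPLL at 0.93 ± 0.29, the ligand-activated transcription factor AHR at 1.00 ± 0.12 and TRERF1, a transcriptional regulator, at 1.03 ± 0.34 followed, with cameraPR adjusted p of 0.00708, 0.00747 and 0.0200. Of these 6 genes only PLEK was called whichever library was left out. Without CD107a negative 1 the cameraPR adjusted p was 0.122 for EED, 0.306 for AHR and 0.909 for TRERF1, without CD107a negative 2 it was 0.416 for HNRNPLL, and without CD107a high 1 it was 0.194 for PCGF1.

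Knockouts that were enriched in CD107a high cells included the call with the smallest p in cameraPR, ATP2B1, the plasma membrane calcium pump that clears calcium from the cytosol, which was 3.80-fold higher there at -1.93 ± 0.58 (cameraPR adjusted p = 8.43e-10). ATP2A2, the pump that returns calcium to the endoplasmic reticulum, had -2.14 ± 0.90, and TBX21, the transcription factor T-bet of natural killer cells, had -2.16 ± 0.77 (cameraPR adjusted p = 9.32e-05 each). MEF2BNB, now named BORCS8, a subunit of the BORC complex that positions lysosomes, had -2.11 ± 0.81 (cameraPR adjusted p = 1.91e-06). STK4, a kinase of the Hippo pathway, was 9.11-fold higher in CD107a high cells at -3.19 ± 1.15 (cameraPR adjusted p = 0.000407), with a mean of 3.05 CPM (reads scaled to library size) in CD107a negative cells. MIOS, a subunit of the GATOR2 complex of amino acid sensing, had -1.74 ± 1.14 (cameraPR adjusted p = 0.000471). All 6 lost their call in some of 16 alternative settings, MIOS in 4 and each of the others in 3. For each gene 3 of these were rank-based cameraPR, camera with an estimated correlation and fry. Those called no gene at all, so these losses are not particular to the 6. TM9SF3 at -0.998 ± 0.25 and the COPII coat subunit SEC23B at -1.12 ± 0.66 had cameraPR adjusted p of 0.00411 and 0.00588, which became 0.345 and 0.357 without CD107a negative 2.

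**Figure D2:**
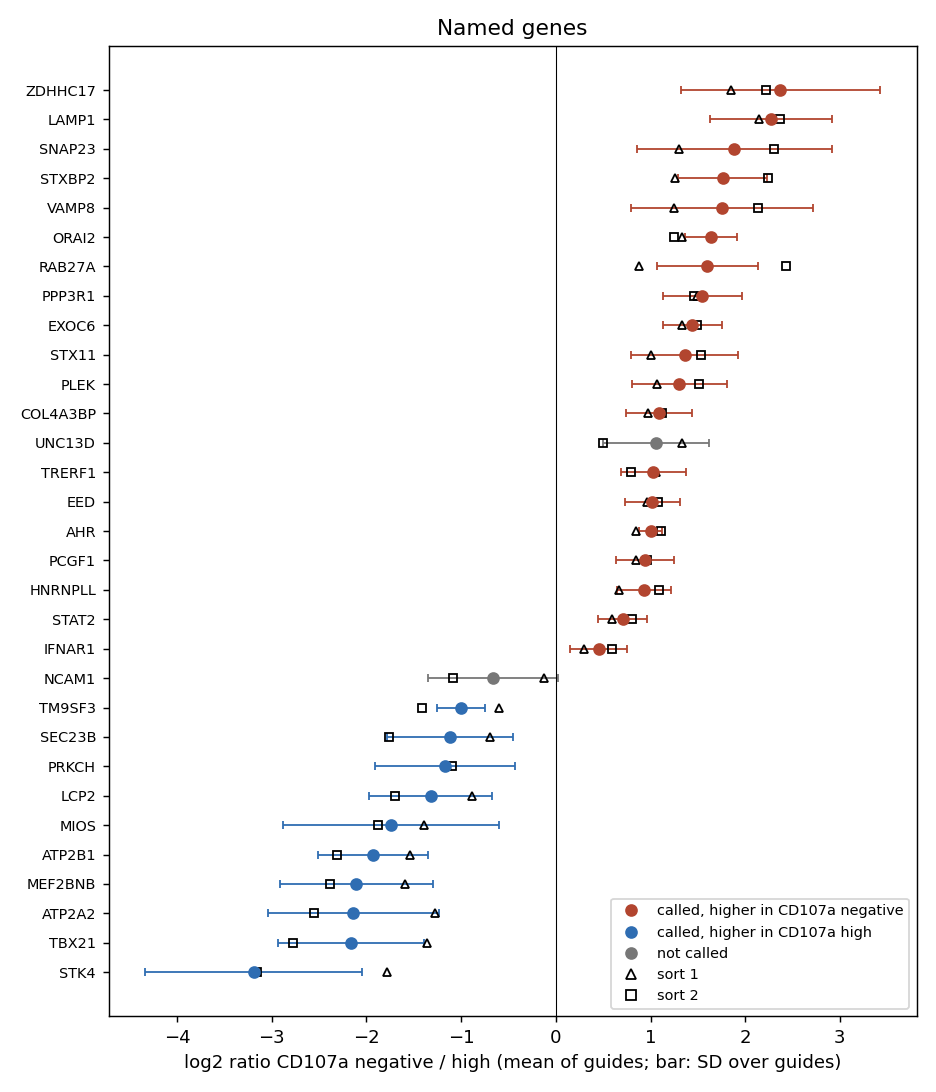
Mean log2 ratio of CD107a negative over CD107a high cells for the named genes, with the SD over guides as the error bar and the values of sorts 1 and 2 as separate marks. The sort values were computed from CPM plus 1 and the mean from the fitted model, so they need not bracket it; LAMP1 lies at 2.27 and STK4 at -3.19.

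Of the 26 measured NK receptors and proximal signalling proteins, 3 were enriched in CD107a high cells and none in CD107a negative cells, over all genes and adjusted over the list alone. They were LCP2, the adaptor SLP-76, at -1.32 ± 0.65, SH2D1B, the adaptor EAT-2, at -1.35 ± 0.50 and VAV1 at -1.48 ± 1.10, with cameraPR adjusted p of 0.00412, 0.00747 and 0.0281. Without CD107a negative 2 these became 0.119, 0.256 and 0.300. The list did not pass its test (cameraPR adjusted p = 0.280), and its median of 0.12 and mean z of -0.23 differed in sign.

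In the Rab geranylgeranylation list, 7 of whose genes kept enough guides to be tested, cameraPR called none over all genes. Adjusted over the list alone, the mevalonate pathway kinases MVK, at 3.30 ± 1.88, and PMVK, at 3.53 ± 1.88 (n = 3 guides each), were higher in CD107a negative cells (cameraPR adjusted p = 0.00199 and 0.00264), and the list had an adjusted p of 0.280. From CPM plus 1, sorts 1 and 2 gave smaller values, 1.80 and 2.34 for MVK and 1.87 and 1.84 for PMVK. The size of both effects is therefore uncertain. The IL-2 receptor list, with 10 tested genes, had a cameraPR adjusted p of 0.834, and IL2RA alone passed over the list alone, at -0.54 ± 0.10 (adjusted p = 0.0293, but 0.555 without CD107a negative 2). The cytosolic ribosomal proteins, with 17 tested genes, had a cameraPR adjusted p of 0.794 with a median of 0.33 and a mean z of -0.12. Adjusted over that list alone, RPS4X passed at -0.74 ± 0.28 (n = 3 guides, cameraPR adjusted p = 0.00867, but 0.243 without CD107a negative 1). No gene was called by cameraPR, over all genes or over the list alone, among the 57 tested mitochondrial ribosomal proteins (list adjusted p = 0.117), 3 V-ATPase subunits (0.280), 22 genes of N-glycan processing and sialylation (0.794), 21 cortical actin regulators (0.834) and 8 subunits of the conserved oligomeric Golgi complex (0.876). The same held for 5 proteasome subunits (cameraPR adjusted p = 0.925, median -0.22, mean z 0.06), 365 olfactory receptors (0.925), 26 genes of HOPS, BLOC and AP-3 (0.994, median -0.03, mean z 0.01) and 27 negative regulators of growth (0.994). Examples were FUT8 at 0.99 ± 0.41, WIPF1 at -2.12 ± 1.02 and MRPL55 at 0.87 ± 0.21, none of which was called.

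In all, cameraPR called 51 of 17883 tested genes at an adjusted p under 0.05, 30 higher in CD107a negative and 21 higher in CD107a high cells, and 1110 genes had an unadjusted p under 0.05. All 51 had the same sign in both sorts, which calling itself favours because it used both sorts together. Against the day 17 cells, 29 of the 30 genes higher in CD107a negative cells were above day 17 in both CD107a negative libraries and 29 were below it in both CD107a high libraries; the exceptions were TRERF1 at -0.07 in CD107a negative 2 and RAB27A at 0.18 in CD107a high 1. Of the 21 others, 20 were below day 17 in both CD107a negative libraries, with SEC23B at 0.06 in CD107a negative 1 as the exception, and all 21 were above it in both CD107a high libraries. By edgeR, 2 single guides passed, one against LAMP1 at 3.08 (adjusted p = 0.0103) and one against STAT2 at 0.97 (adjusted p = 0.0112), of 72497 tested. Splitting the same libraries by sort number called 0 genes with cameraPR, 0 with DESeq2 statistics and 0 with rank aggregation (826 at an unadjusted p under 0.05), and 247 pseudo-genes made of 4 non-targeting guides each gave 0, 0 and 0 calls (16 at an unadjusted p under 0.05). The pseudo-genes are a weak check, because they are few and their guides vary less than targeting guides (SD of log2 0.459 against 0.956).

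The replicates were 2 sorts of one transduced cell pool, so the p-values may measure only technical spread, and agreement across all genes was low. Mean log2 ratios of the sorts had a Pearson's r of 0.134 and a Spearman correlation of 0.116 across genes, which are not independent replicates. Among the called genes r was 0.940, a value that calling itself raises. Of the 51 calls, 11 were kept whichever sorted library was left out: STAT2, STXBP2, LAMP1, ZDHHC17 and PLEK in CD107a negative cells and ATP2B1, MEF2BNB, ATP2A2, TBX21, STK4 and MIOS in CD107a high cells. The other 40 were lost without at least 1 library, and the call count fell to 19 without CD107a negative 1, 18 without CD107a negative 2, 25 without CD107a high 1 and 37 without CD107a high 2. It fell to 9 without each gene's strongest guide, and to 0 with rank-based cameraPR, camera with an estimated correlation and fry, whose smallest adjusted p were 0.820, 1.00 and 0.670. The non-targeting guides lay slightly toward CD107a negative cells, with a median log2 of 0.07 against 0.01 for targeting guides.

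The unsorted libraries were compared with the plasmid library to describe which guides were present after selection and which were lost during growth. These libraries have no replicate, so the differences have no replicate check and no p-value, and all values are relative to the median of the non-targeting guides. On day 17, 4965 of 19100 genes were at or below -1 on the log2 scale and 14 were at or above 1, against 16 of 990 non-targeting guides at or below -1. The latter are single guides and not gene means. Of the 374 olfactory receptors, 69 were also at or below -1, so 4965 is not a count of genes needed for growth. Among genes whose guides all fell, the lowest was ALDOA, the glycolytic aldolase, 23.3-fold below the plasmid library at -4.54 ± 0.07. The chaperones HSPA8 and HSPA5 were at -4.53 ± 0.26 and -4.48 ± 1.05, and the ribosome assembly factor EIF6 was at -4.49 ± 0.28. BUB3 of the spindle checkpoint, the splicing factor SF3B1, CNOT1, the cap-binding NCBP1, the proteasome subunit PSMB4 and the nuclease DNA2 completed the 10 lowest, between -4.46 and -4.39. All 10 had a mean under 1 CPM on day 17, so the pseudocount limits their values and their order.

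By list, the proteasome had the lowest median, -3.41, with 29 of 31 genes at or below -1, and was followed by the cytosolic ribosomal proteins at -3.15 (72 of 76) and the V-ATPase at -3.06 (16 of 16). The medians of Rab geranylgeranylation at -2.05 (11 of 13), IL-2 receptor signalling at -1.99 (11 of 13), cortical actin regulators at -1.70 (19 of 27) and mitochondrial ribosomal proteins at -1.64 (63 of 77) lay, like the first 3, below all 10000 random lists of the same size matched on plasmid abundance. IL2RG, the common gamma chain of the receptor for the cytokine these cells grow on, was at -3.62 ± 1.02 and STAT5B at -2.98 ± 0.88, while IL2RA was at 0.07 ± 0.61. The conserved oligomeric Golgi complex was at -1.78 (7 of 8 genes at or below -1, percentile 0.12) and de novo ceramide synthesis at -1.06 (7 of 14, percentile 1.48), with KDSR at -1.98 ± 0.79 and SPTLC2 at -1.82 ± 0.24 (n = 3 guides). HOPS, BLOC and AP-3 had a median of -0.90 (percentile 2.19) and SNAREs and SM proteins one of -0.80 (percentile 4.02), in which SCFD2 was at -3.81 ± 0.58.

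The median over all genes was -0.65. The exocyst was at -0.90 (percentile 10.5), palmitoyl transferases and partners at -0.80 (8.65), N-glycan processing at -0.76 (18.7), negative regulators of growth at -0.73 (24.1), depalmitoylating enzymes at -0.70 (35.6) and olfactory receptors at -0.61 (88.8). PKC, calcium and ERK signalling was at -0.58 (percentile 75.3), cytotoxic granule exocytosis at -0.57 (76.1), fatty acid supply at -0.51 (89.6), sphingolipid conversion at -0.50 (96.1), NK receptors at -0.41 (99.4) and the LAMP1 and NCAM1 pair at -0.39 (81.6). Single members went further, such as ZDHHC8 at -1.86 ± 0.65 and the CMP-sialic acid synthetase CMAS at -2.91 ± 1.40. The count of 4965 fell to 2946 with a pseudocount of 5 CPM and to 2449 without centring on non-targeting guides, and the 14 became 97 without centring.

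**Figure D3:**
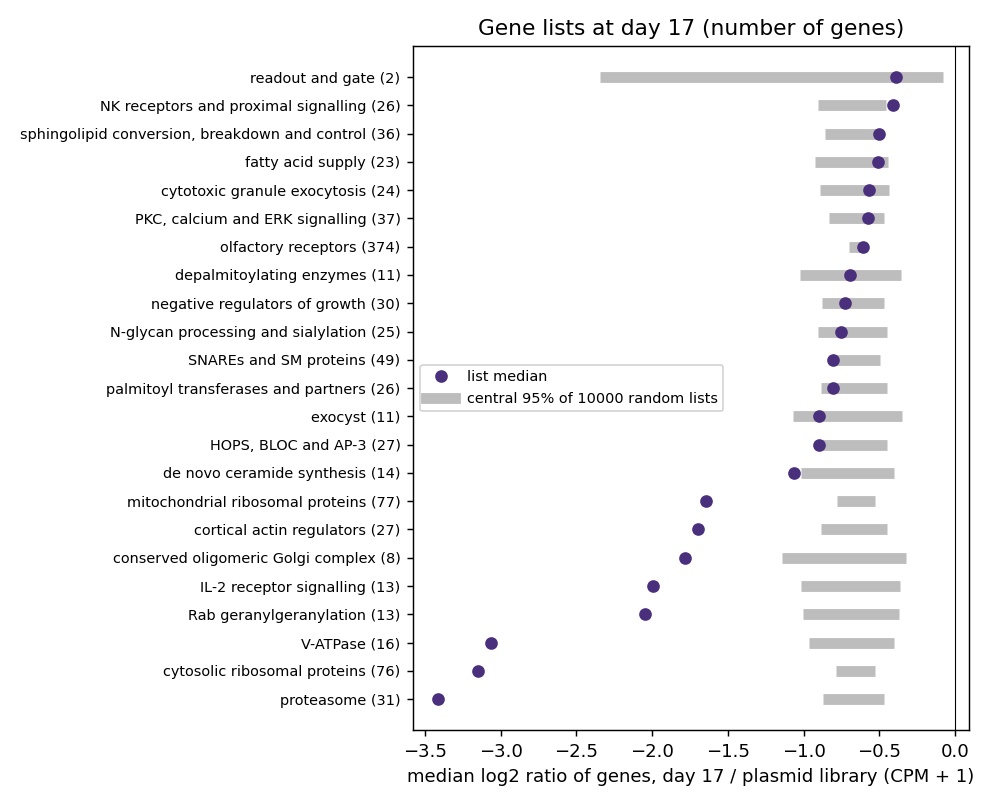
Median log2 ratio of day 17 over the plasmid library for each fixed gene list, beside the range holding 95% of 10000 abundance-matched random lists. The proteasome, at -3.41, lies lowest and the LAMP1 and NCAM1 pair, at -0.39, highest.

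Guides against genes of type I interferon signalling were the highest on day 17. The receptor subunit IFNAR2 was 14.4-fold above the plasmid library at 3.85 ± 0.09, the kinase TYK2 was at 3.37 ± 0.26, IFNAR1 at 3.13 ± 0.83, STAT2 at 2.72 ± 1.04 and IRF9 at 2.58 ± 0.51. On day 9 the same genes lay between -0.46 and -0.13. IFNAR1 and IFNAR2 are on chromosome 21, whose other genes had a median of 0.17 from day 9 to day 17, against -0.30 over the genes of all other chromosomes together. Chromosome 10, at 0.09, was the only other chromosome with a median above 0. The calcium pump ATP2B1 at 1.36 ± 0.57, TMEM173, now named STING1, the adaptor of cytosolic DNA sensing, at 1.29 ± 0.39, the splicing regulator MBNL1 at 1.27 ± 0.66 and the sphingomyelin synthase SGMS1 at 1.25 ± 0.11 followed.

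**Figure D4:**
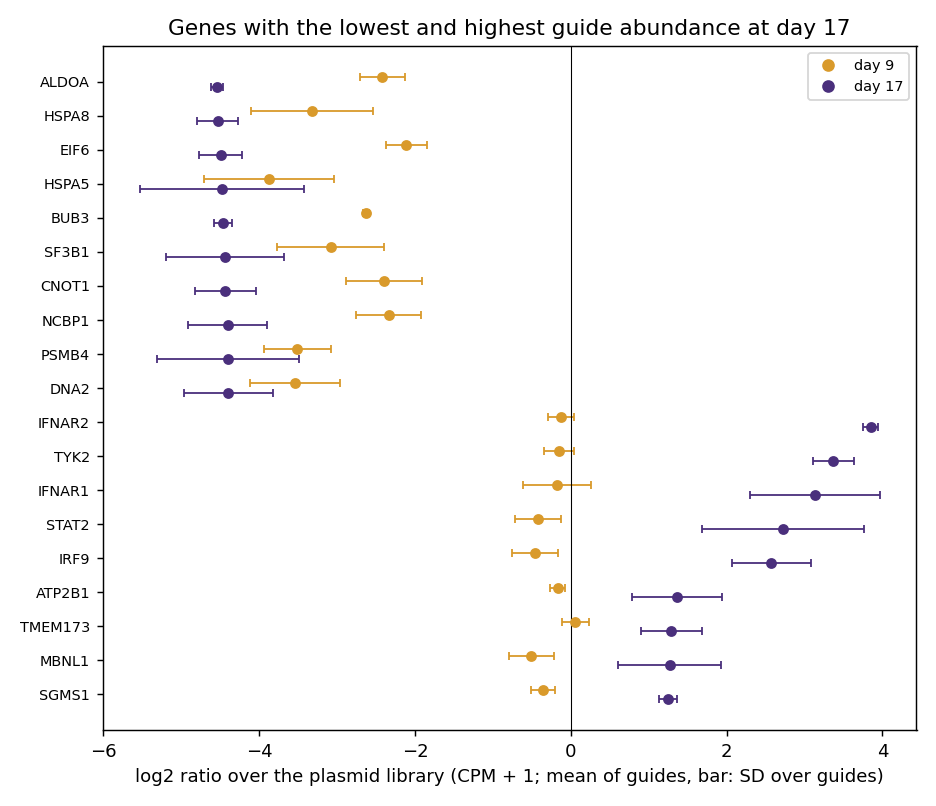
Mean log2 ratio over the plasmid library on day 9 and day 17 for the lowest and the highest genes, with the SD over guides as the error bar. IFNAR2 moved from -0.13 to 3.85 and ALDOA from -2.42 to -4.54.

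On day 9, 1400 of 19100 genes were at or below -1 and 0 were at or above 1. From day 9 to day 17, 1886 of 18925 genes were at or below -1 and 36 were at or above 1. The median on day 9 was already -2.44 for the proteasome and -1.72 for IL-2 receptor signalling, but -0.34 for the mitochondrial ribosomal proteins, whose median on day 17 was -1.64. KDSR, the reductase of ceramide synthesis, was at 0.07 on day 9 and -1.98 ± 0.79 on day 17. With a pseudocount of 5 CPM the day 9 count fell to 804 and the count from day 9 to day 17 to 550, and without centring the day 9 count was 913.

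Whether knockouts that slowed growth also moved in the sort was asked across the 17883 genes in both comparisons. Pearson's r between day 17 over the plasmid library and CD107a negative over high was 0.0443 (95% bootstrap interval over genes 0.0208 to 0.0667) and the Spearman correlation was 0.00375. Among the 14124 genes above -1 on day 17, r was 0.00853 and the Spearman correlation was -0.0094. On day 17 the granule exocytosis genes called in the sort were at 0.21 for STXBP2, -0.43 for RAB27A, -0.56 for STX11, -0.57 for VAMP8 and -0.86 for SNAP23, and LAMP1 was at -0.13, beside the median of -0.65 over all genes.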

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

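All of the alternatives here were planned, apart from leaving out libraries for genes and lists outside the naming rule, which was added after the result was seen. Over all settings, 375 values for single genes and lists kept their direction and their side of the threshold, 172 lost the threshold, and none reversed; of the counts and correlations, 68 stayed within 1.5 times or within their interval and 41 moved further. The 51 called genes were 51 with DESeq2 size factors, 51 with total counts, 52 with non-targeting scaling, 42 without a guide filter, 50 at a mean of 5 CPM, 74 with DESeq2 Wald statistics and 39 with rank aggregation, sharing 51, 51, 51, 41, 50, 46 and 32 with the main set. They were 9 without each gene's strongest guide, 4 in the CD107a negative and 5 in the CD107a high direction, and 0 in each direction with rank-based cameraPR, camera with an estimated correlation and fry. By construction 4 guides cannot reach an unadjusted p under 0.000637 in the rank test, whereas the largest p of a gene called by parametric cameraPR was 9.14e-05, and camera and fry had 2 residual degrees of freedom. Genes higher in CD107a high cells were 36 with DESeq2 Wald statistics. Leaving out 1 sorted library gave 18 to 37 called genes, 9 to 21 of them higher in CD107a negative cells (9 without CD107a negative 1 and without CD107a negative 2, 15 without CD107a high 1) and 9 to 16 higher in CD107a high cells (10 without CD107a negative 1, 9 without CD107a negative 2 and 10 without CD107a high 1). The 2 called guides became 0 without a filter, 4 at 5 CPM and 2764 with DESeq2 Wald statistics, and 0 to 16 on leaving out a library (16 without CD107a negative 1, 3 without CD107a negative 2, 1 without CD107a high 1, 0 without CD107a high 2). The 3 called lists became 0 with an estimated correlation and 2 to 3 on leaving out a library. The correlation of the sorts was 0.163 at 5 CPM, and that of growth with the sort was 0.00853 above -1. Genes at or below -1 were 2946 with a pseudocount of 5 and 2449 without centring on day 17, 804 and 913 on day 9, and from day 9 to day 17 they were 550 with a pseudocount of 5 and 1195 at 5 CPM. Genes at or above 1 without centring were 97 on day 17 and 75 from day 9 to day 17, and with a pseudocount of 5 they were 20 in the latter. Apart from the limits named, the cause was not tested. The medians of gene lists on day 17 were not recomputed in another way, and NCAM1 has no value at 5 CPM because too few guides remain.

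The sort numbers were not shown to pair the libraries: the deviations of same-numbered libraries had a correlation of 0.000962 over guides. With the sort number as a replicate block, 61 genes were called, 49 of them among the 51, with 36 in the CD107a negative and 25 in the CD107a high direction, and 11 guides and 3 lists passed. The rank test, camera with an estimated correlation and fry have p too large to call any single gene here, and thin coverage of depleted guides limits the sort comparison for genes such as V-ATPase subunits, 3 of which could be tested.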

Other observations

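The lists and tests here were chosen after the result was seen, except the tests of the lysosomal genes against matched lists and against mTORC1, which were fixed before their own results were seen. The tests of the far side of chromosome 21 were split off after the first test of its sides was seen. Sets built around genes already called in the sort have a small cameraPR p partly for that reason, so these p-values are descriptive. Among knockouts enriched in CD107a high cells, several belong to complexes on the lysosomal surface. All 3 measured genes of GATOR2, an activator of nutrient sensing, were called there: MIOS at -1.74 ± 1.14, WDR59 at -1.30 ± 0.12 and WDR24 at -1.08 ± 0.67 (cameraPR adjusted p = 5.79e-12 for the set, 0.0834 with an estimated correlation). LAMTOR2 at -0.80 ± 0.64 and RRAGC at -0.99 ± 0.28 were called among the 9 genes of Ragulator and the Rag GTPases (cameraPR adjusted p = 1.45e-05 for the set, 0.0834 with an estimated correlation), and MEF2BNB among 7 genes of BORC (1.92e-05, 0.0834 with an estimated correlation). Without single libraries the gene calls other than MIOS and MEF2BNB were lost, with a highest cameraPR adjusted p of 0.300 for WDR59 and 0.416 for WDR24 without CD107a negative 2, and 0.439 for LAMTOR2 and 0.584 for RRAGC without CD107a negative 1, while the 3 sets passed in each case. GATOR1 and KICSTOR, which oppose GATOR2, had a median of 0.43 in the other direction with 0 of 7 genes called (cameraPR adjusted p = 0.00967 for the set, 0.301 with an estimated correlation, 0.0711 without CD107a negative 1 and 0.146 without CD107a high 2). The calcium pumps had ATP2B1 and ATP2A2 called of 8 genes (cameraPR adjusted p = 0.000103, 0.0834 with an estimated correlation), although their median was 0.13 against a mean z of -0.84.

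In CD107a negative cells, RCE1 at 1.26 ± 0.71 and ICMT at 1.75 ± 0.70, which finish the processing of prenylated proteins, were called, 2 of 3 measured CAAX processing genes (cameraPR adjusted p = 0.00243 for the set, 0.186 with an estimated correlation); without CD107a negative 2 the cameraPR adjusted p was 0.788 for RCE1 and 0.642 for ICMT. The polycomb set had EED and PCGF1 called of 8 genes (cameraPR adjusted p = 2.30e-07, 0.0834 with an estimated correlation), with SUZ12 at 0.92 ± 0.38 and EZH2 at 0.70 ± 0.65 not called. MADD, an exchange factor for Rab GTPases, at 1.44 ± 1.02, and KLRD1, the CD94 receptor chain, at 1.17 ± 0.14, were called as well. Both were lost whichever library was left out, with the highest cameraPR adjusted p at 0.584 for MADD without CD107a negative 1 and 0.836 for KLRD1 without CD107a negative 2.

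From day 9 to day 17 the type I interferon set had a median of 3.43, above all matched random lists, and 24 of its 24 guides were at or above 1. Its genes were named for high means with all guides above the plasmid library. The count of guides was thus largely fixed and cannot decide on a few expanded clones. Over day 9 the set's median was at least 3.15 in each sorted library, so the day 17 library alone does not account for the rise. The median of IFNGR1 and JAK2, of the interferon gamma receptor without IFNGR2, a neighbour of IFNAR1, was -0.19 (percentile 63.7), which is in line with selection against the response to type I interferon; the cytosolic DNA sensing set was at 1.05, with STING1 at 1.24, CGAS at 1.08, IRF3 at 1.03 and TBK1 at -0.35, and RNA sensing at -0.28 (percentile 41.9). Interferon itself was not measured. In the sort the set had a cameraPR adjusted p of 4.98e-20 (0.186 with an estimated correlation), and the gamma receptor, DNA and RNA sensing sets had 0.587, 0.894 and 0.633. The type I interferon set was chosen after STAT2 and IFNAR1 had been called there, so its small p adds no support.

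Genes of chromosome 21 were higher together over time, with a median of 0.17 for 208 genes from day 9 to day 17 (highest of 10000 abundance-matched lists -0.17). They were also higher in CD107a negative cells, with 0.27 for 203 genes (highest matched list 0.11). Guide abundance alone thus did not bring such shifts in other genes. The chromosome was chosen after its high values were seen, so its place above matched lists is descriptive and excludes no cause. In the sort, over 205 genes with IFNAR1 and IFNAR2 included, cameraPR gave 5.76e-08, adjusted 1.32e-06 over 23 chromosomes and 0.0947 with an estimated correlation. A candidate explanation is loss of the chromosome from a cut to its end in cells that thereby lose IFNAR1 and IFNAR2. Over time the 80 genes on the centromere side exceeded the 127 on the far side by 0.49, as large as in 1.45% of rotations of the gene order, which is in line with that for the centromere side, but in the sort the difference of 0.12 (5.94% of rotations) cannot be told apart from none. The far side itself stayed above matched lists, at 0.0783 over time (highest matched list -0.13) and 0.24 in the sort (highest 0.16). A loss from the cut to the end does not give this, and losses of another extent were not examined. Fewer copies of the chromosome in these cells could lower the cost of cutting, and copies were not measured. Non-targeting guides have no target to cut, so a lower cost would bring genes at most to their level. Over time that level was set to 0, and the centromere side was at 0.56, in single libraries. In the sort the level was 0.07, against 0.36 on the centromere side and 0.24 on the far side. These values argue against a lower cost alone, but the far side over time, at 0.0783, leaves it open. Chromosome 10, without IFNAR genes, also had a median above 0 over time (0.09). Whether other genes on it whose guides rose in culture play a like part was not examined, so it decides nothing here.

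The 19 measured lysosomal genes (GATOR2, Ragulator, Rag and BORC) had a median of -0.76 in the sort, and 13 were negative in both sorts. Of lists matched on depletion, 95% lay between -0.22 and 0.22, so depletion by day 17 alone did not bring such a shift in other genes. The list was chosen after its members were seen in CD107a high cells, so its place outside that range was expected and excludes no cause. From day 9 to day 17 the medians were 0.76 for Ragulator and Rag (percentile 100) and 0.33 for GATOR2 (percentile 99.98), but -0.26 for BORC (percentile 59.1), and a link of this gain in culture with the shift was not tested. Lower mTORC1 activity may underlie the shift, but the 3 genes MTOR, RPTOR and MLST8, with a median of -0.57, gave a cameraPR p of 0.218 (set adjusted p = 0.291), which leaves it open. No biological explanation was tested beyond this.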
